A study of Mus musculus with 6 samples.

How the data were processed

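Ribosome-bound mRNA was recovered from whole mouse brain by RiboTag, in which cells that express Cre carry an epitope-tagged ribosomal protein and their ribosomes are pulled down with an antibody against the tag. Here Cre was driven by Gfap, an astrocyte gene, and per the labels the captured RNA came from astrocytes with some neurons and oligodendrocytes. The mice received a control diet or a diet with 1200 ppm PLX5622, an inhibitor of the receptor Csf1r that removes microglia, for 1 month. Each diet had 3 libraries, which the labels call biological replicates, and non-stranded mRNA libraries were sequenced. Because strand was not kept, reads of overlapping antisense genes cannot be told apart.

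The TPM values of the 6 libraries were made by the authors, and the 6 columns sum to the same total. Per the submitters' processing notes, STAR 2.7.10a, featureCounts from Subread 2.0.1, DESeq2 1.32.0, R 4.1.0 and the mouse build mm39 were used; the annotation, the gene lengths and any filter are not given in the sources used here. A second table, per its file headers in the format of DESeq2 output, holds the authors' own comparison of the diets. Its baseMean column is, per the file headers, the authors' signal per gene, a mean of normalized counts over libraries. Its fold changes and their standard errors are on the log2 scale, as deposited by the authors. Its test statistic is a score, the deposited log2 fold change over its standard error. Its p-value columns were deposited by the authors as raw and adjusted values, and the adjusted ones equal a Benjamini-Hochberg adjustment over all 20062 genes within 2.8e-15. The table does not name its numerator. A negative value was read as lower on PLX5622, the sign under which the deposited fold changes correlate positively with the labelled difference between diets.

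TPM carries no read depth, so the depth of each library is unknown and no counting interval is given. The baseMean values sum to 48090000, which is the mean library size on the authors' normalized scale. A count test needs counts, so the comparison by label used limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a mean-variance trend in the empirical Bayes step, for genes with a mean of at least 1 TPM over the 6 libraries. Of 26264 genes, 6200 were at 0 in all libraries and 13084 were tested. Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of genes with low TPM. No library or column was left out.

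Gene lists for sterol pathways, brain cell types, cell states and the Csf1r pathway, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The lists cover cholesterol synthesis, sterol regulation and uptake, cholesterol efflux and turnover, fatty acid synthesis, microglia, border macrophages, astrocytes, neurons, oligodendrocytes, their precursors, endothelium, mural cells, ependyma with choroid plexus, reactive astrocytes, interferon response, immediate early genes, glucocorticoid response, circadian clock, ER stress, heat shock, xenobiotic response and the Csf1r axis, with sex-linked and blood genes as checks. Lists with 3 or more tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. The authors' statistic was tested over the same lists with cameraPR, for genes with a baseMean of at least 10, as a choice made after seeing the data. It uses the preset correlation, and no estimated one can be had from a table without libraries. Levels of a list are the mean log2(TPM + 1) of its tested members per library, compared by an exact two-sided permutation test whose smallest possible p is 0.1, with an exact 90% interval from the lowest to the highest of the between-diet differences.

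The rule named the 6 genes with the smallest p in each direction where fewer pass the threshold, a fixed set of sterol, microglial and astrocyte genes, and from each list its called members or else the 2 with the highest mean TPM; predicted and clone-based names were not used. Some genes that the rule takes are not reported here, and no others took their place. Other genes named in the text were chosen after their values were seen. The same limma step was tested on simulated values for the comparison of diets with 13084 genes and 200 changed genes. It recovered 69% of genes changed by 1 on the log2 scale, 97% at 2 and 98.5% at 3, with 9, 9 and 8 false calls, and made 0 calls where no gene was changed. A shift of 0.5 in the cholesterol synthesis list was called in 20 of 20 simulated runs with independent genes. The simulated values carry no effects shared by the genes of a library. In the data this list had an estimated correlation of 0.696, so the simulated rates need not hold here.

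Each of the 10 splits of the 6 libraries into groups of 3 was set against the authors' deposited log2 fold changes across genes with a baseMean of at least 50. The microglial check of the diet went against the label of a library in each group, so libraries are named by their labels throughout and the labels were kept in every main comparison. Alternatives planned beforehand were other pseudocounts, filters, scalings, array weights, variants of the empirical Bayes step, a replicate block and leaving out each library. Added later were the fit without the libraries labelled control 3 and PLX5622 3, the fit with these exchanged, and the removal of genes that overlap ribosomal RNA sequence. Transcript lengths for 1 check came from the longest GENCODE M21 transcript of each symbol, matched for 97.8% of tested genes. This annotation is of another build than the authors', so it was used for lengths only and no coordinates are given.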

Results

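The data are gene expression values of Gfap-Cre; RiboTag brain libraries, 3 from mice on control diet and 3 from mice on PLX5622 diet at 1200 ppm for 1 month. The series asks if the drug shifts cholesterol pathways in astrocytes, which make most cholesterol of the adult brain, and in the neurons and oligodendrocytes captured with them. Astrocyte transcripts were abundant: the 16 astrocyte list genes summed to 34180 ± 5293 TPM in the libraries labelled control and 47390 ± 2608 TPM in those labelled PLX5622 (SD, n = 3). The 15 neuron genes summed to 2112 ± 199.6 and 1434 ± 359.5 TPM, and the 14 oligodendrocyte genes to 4069 ± 607.7 and 3891 ± 526.4 TPM. Between 12871 and 13181 genes reached 1 TPM in a library, and read depth is unknown because TPM does not keep it.

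Microglial transcripts, used here as a check of the diet, did not follow the labels of 2 libraries. The pulldown targets ribosomes of cells with Gfap-driven Cre, so these low values need not track the number of microglia, which is unknown here. Csf1r, the receptor that PLX5622 inhibits, was at 4.33 and 4.27 TPM in the libraries labelled control 1 and control 2 but at 0.118 TPM in the one labelled control 3. In the libraries labelled PLX5622 1 and PLX5622 2 it was at 0.811 and 0.0208 TPM, and in the one labelled PLX5622 3 at 2.05 TPM. Tmem119, a microglial surface protein, was at 3.02, 2.03 and 0.151 TPM in the control libraries and at 0.617, 0.0761 and 1.48 TPM in the PLX5622 libraries, in order of their labels. Cx3cr1, the microglial fractalkine receptor, was listed at 0 in the library labelled PLX5622 2 and at 0.122 TPM in the one labelled control 3, against 1.70 and 2.05 TPM in the other two control libraries. The difference by label in Csf1r was −0.83 ± 0.59 (log2, SE, n = 3) and in Tmem119 −0.57 ± 0.44, with limma adjusted p = 0.380 and 0.421. P2ry12, a microglial purinergic receptor, differed by −0.10 ± 0.18.

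**Figure D1:**
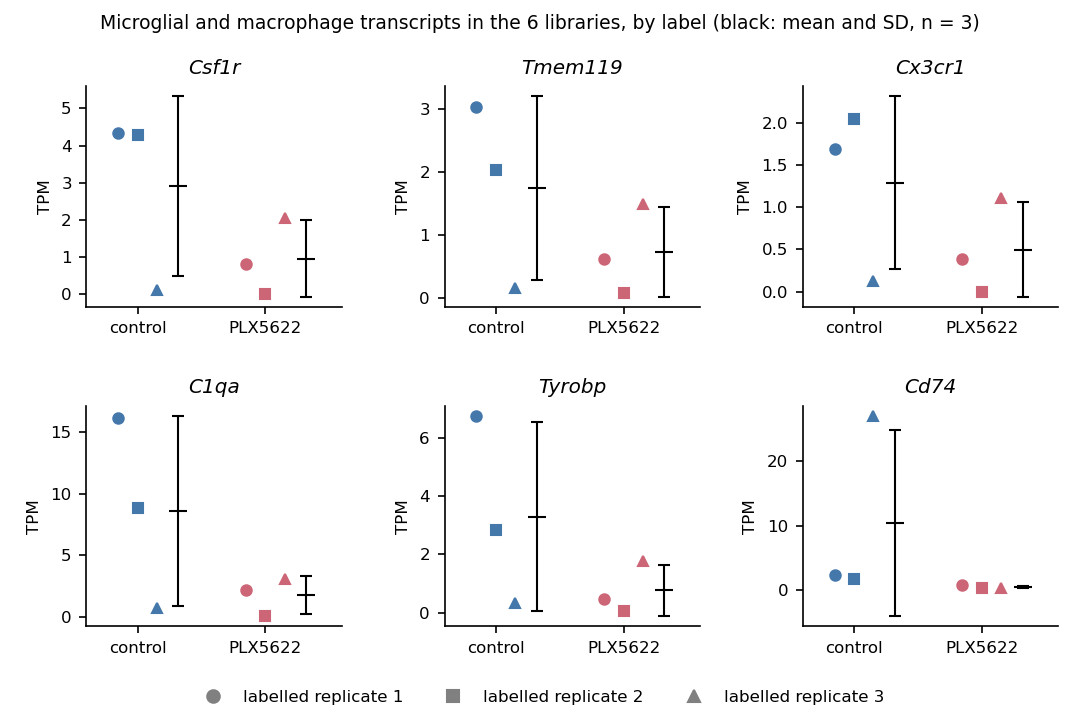
TPM of 6 microglial or macrophage genes (y axes, linear) in the libraries by labelled diet (x axis), with marker shape for the labelled replicate and the mean and SD of 3 libraries in black. For Csf1r the library labelled control 3 sits at 0.118 TPM and that labelled PLX5622 3 at 2.05 TPM, and for Cd74 the library labelled control 3 stands at 27.0 TPM.

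The fold changes in the authors' deposited table did not correspond to the labelled grouping of the TPM columns. Across 13179 genes outside the microglia and macrophage lists and the authors' called genes, they correlated with the difference between the labelled groups at r = 0.567, with a median absolute difference of 0.18 on the log2 scale. With the libraries labelled control 3 and PLX5622 3 exchanged, the correlation was 0.9998 and the median absolute difference 0.0123. These are correlations across genes, which are not independent replicates. In a regression of the authors' deposited fold changes on the 6 libraries, control 1, control 2 and PLX5622 3 had negative weights (−0.345, −0.352 and −0.28). The weights of control 3, PLX5622 1 and PLX5622 2 were positive (0.366, 0.314 and 0.297). Values from the authors' table and values by label are therefore given separately.

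**Figure D2:**
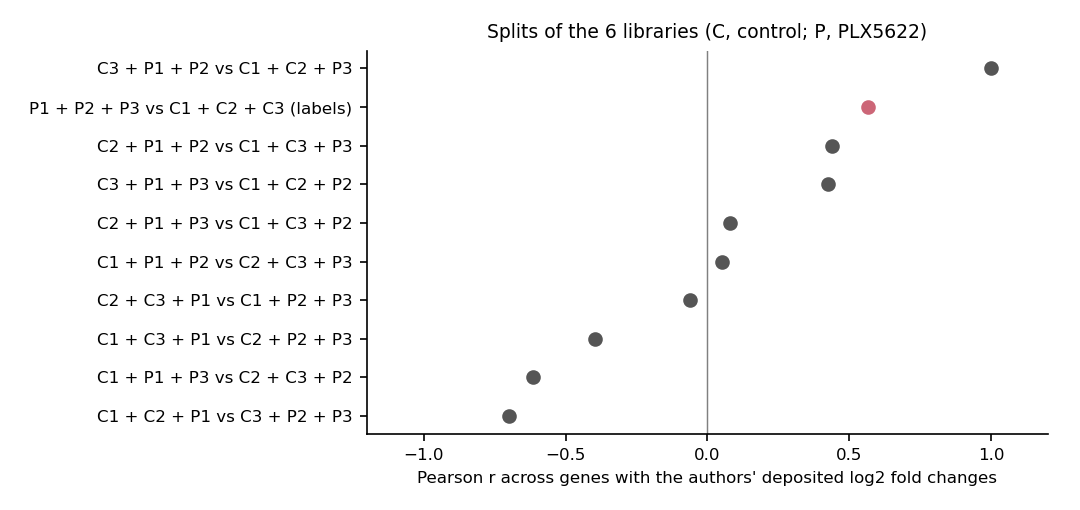
Pearson correlation across genes (x axis) between the authors' deposited log2 fold changes and the log2 difference between groups for each of the 10 splits of the 6 libraries (y axis; C, control; P, PLX5622; labelled split in red). The labelled split lies at 0.567 and the split that exchanges C3 and P3 at 0.9998.

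The authors' deposited table holds 14 genes called lower and 0 called higher at a DESeq2 adjusted p of 0.05 among 20062. Its fold changes set the libraries labelled control 3, PLX5622 1 and PLX5622 2 against the others. Whether these calls are an effect of PLX5622 therefore depends on which headings are right, which stays open. All 14 are known mainly from myeloid or other blood-derived cells. In the authors' table, Stab1, a macrophage scavenger receptor, fell by 4.64 on the log2 scale, and Tmem119 by 3.10 (SE 0.62, DESeq2 adjusted p = 0.00242). Trem2 and Tyrobp, a receptor and its signalling adaptor, had deposited log2 fold changes of −3.18 and −3.92 in the authors' table, and Itgam and Laptm5 of −3.78 and −2.98. The other called genes in the authors' deposited table were Arhgap45, Bin2, Nckap1l, Ncf1, Fcer1g, Fcgr3, Csf3r and Abi3, the last of which fell by 2.13 on the log2 scale, the smallest change of the 14. Of 21 microglia list genes in the authors' table, 20 were negative, the median was −3.30, and 19 had p under 0.05 (cameraPR adjusted p = 4.45e-95). The cameraPR values use the preset correlation: in the limma fit with the libraries labelled control 3 and PLX5622 3 exchanged, 12 of 22 lists were called by camera with that correlation and 0 with an estimated one (lowest adjusted p = 0.0607, for microglia). Leaving out a single library turned the sign of the level difference of 13 of 22 lists in that grouping and of 5 by label. Of the 14 called genes 5 are in that list, and 8 had a mean under 1 TPM. The authors' table gave Csf1r at −3.61 (SE 1.24, 95% interval −6.04 to −1.17), which missed its adjusted threshold. Over all genes, the authors' deposited table had 170 with p under 0.05 (0.847%) where 1003 would be expected by chance.

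By label, no gene passed: limma called 0 genes higher and 0 lower among 13084, against 14 in the authors' table from DESeq2. These counts are not alike, since 8 of the 14 had a mean under 1 TPM and were not tested by limma. With the libraries labelled control 3 and PLX5622 3 exchanged, limma also called 0 genes. An unadjusted limma p under 0.05 was reached by 2974 genes, 1925 higher and 1049 lower, where 654.2 would be expected by chance. The smallest adjusted p by limma was 0.116, for Snora28, a small nucleolar RNA with 0.25 ± 0.217 TPM on control label and 2.15 ± 0.186 TPM on PLX5622 label (SD of 3 libraries). It lies near the counting floor: in the authors' table its baseMean was 2.99 and its log2 fold change 1.15 (SE 1.38). Others in the higher direction were Sptbn1, a spectrin, with 22.8 ± 8.49 against 52.9 ± 13.1 TPM, and Etnppl, a phosphoethanolamine lyase enriched in astrocytes, with 85.9 ± 7.78 against 147 ± 32.5 TPM. Ppp1r9a differed by 1.14 ± 0.25 (log2, SE). In the lower direction stood Smim18 (−1.32 ± 0.18), Spink8 (−1.83 ± 0.28), Rprml (−1.27 ± 0.20), Sult2b1 (−1.10 ± 0.18), Grp, a neuropeptide (−1.15 ± 0.19), and Arhgdib (−0.93 ± 0.15), all with limma adjusted p = 0.205. In the authors' deposited table none of these 10 passed, and Sptbn1 and Ppp1r9a had the opposite sign (−0.066 and −0.16). A single library decides the count: limma called 2600 genes higher and 1154 lower without the one labelled control 2, and 1 higher (Snora28) and 35 lower without the one labelled PLX5622 1. The control libraries left without control 2 deviate from the mean of all libraries against transcript length (r = −0.475 and −0.447 across genes). The PLX5622 libraries deviate with it (0.215 to 0.422), so diet and this length trend cannot be told apart without control 2. Without the libraries labelled control 3 and PLX5622 3, a choice made after seeing the data, limma called Mir7662 and Snora28 higher and 12 genes lower. The 12 are myeloid genes: Ctss, C1qa, C1qb, C1qc, Csf1r, Fcrls, Selplg, Trem2, Tyrobp, Laptm5, Fcer1g and Fcgr3, of which 5 are also among the authors' calls. Those libraries were left out because of their microglial transcripts, so calls of such genes are expected from the choice and are no separate evidence.

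Cholesterol synthesis, the question of the series, was not called in either direction by label. Sqle, squalene epoxidase, stood at 108 ± 24.1 TPM in libraries labelled control and 135 ± 30.7 TPM in those labelled PLX5622 (SD, n = 3), a difference of 0.30 ± 0.21 (log2, SE). Of 19 tested members 0 passed over all genes and 0 when adjusted over the list alone, 14 were positive, and the median was 0.21 (camera adjusted p = 0.424). Over all tested genes the median by label was 0.089, and −0.0068 after size-factor scaling. Counts of positive members, medians and level differences by label are therefore not centred on 0, while camera compares a list with all other genes. In the authors' table the median over all genes was −0.017. The list level differed by 0.17 (exact p = 0.4; exact 90% interval −0.32 to 0.52). Of 20 members in the authors' deposited table, 18 were negative, with a median of −0.12 (cameraPR adjusted p = 5.75e-04), and none had p under 0.05. Sqle was at −0.15 (95% interval −0.60 to 0.29) in the authors' table. Hmgcs1, with 475 ± 179 and 609 ± 125 TPM by label, and Msmo1, with 419 ± 53 and 489 ± 73.4 TPM, were at −0.085 and −0.15 in the authors' table. The list level of the libraries, 6.36, 6.79 and 6.51 for control and 6.82, 6.47 and 6.89 for PLX5622 in order of their labels, spread within each label by more than the labels differed. Without the library labelled PLX5622 2 the list was called higher by camera (adjusted p = 0.0121; adjusted p = 0.648 with an estimated correlation). After a loess correction on transcript length its median by label was 0.12 (camera adjusted p = 0.318). With the libraries labelled control 3 and PLX5622 3 exchanged, the list level differed by −0.083, and by 0.020 once the library labelled PLX5622 3 was left out.

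**Figure D3:**
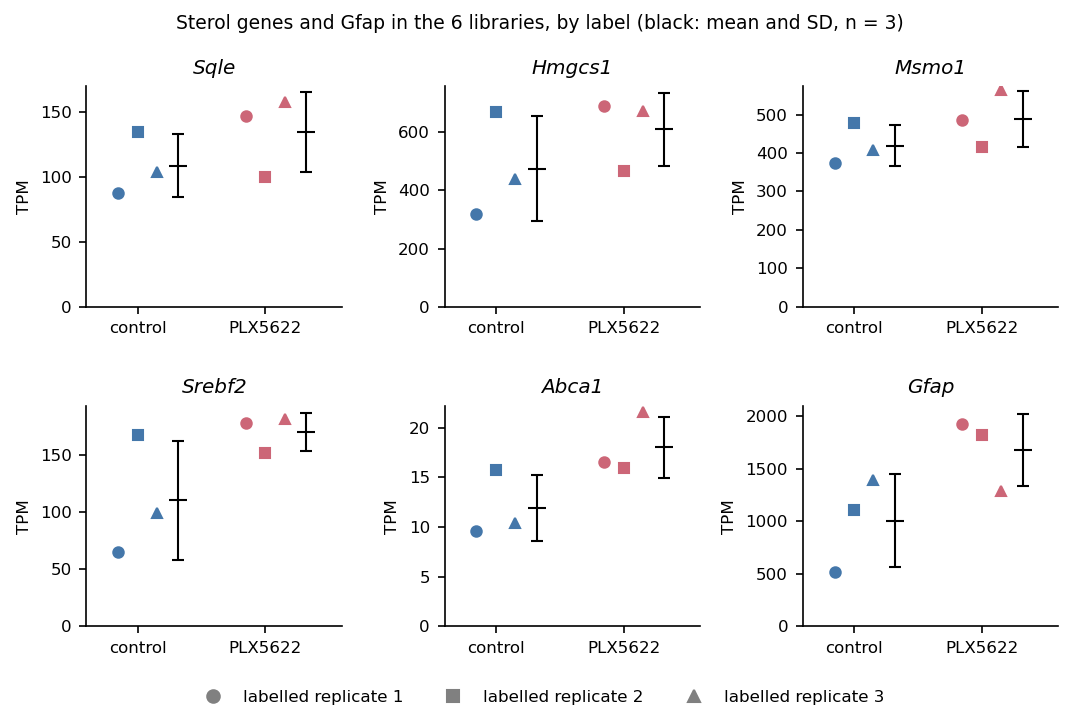
TPM of 5 sterol genes and Gfap (y axes, linear) in the libraries by labelled diet (x axis), with marker shape for the labelled replicate and the mean and SD of 3 libraries in black. Sqle spans 87.2 to 135 TPM in the libraries labelled control and 99.8 to 158 TPM in those labelled PLX5622.

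Genes of sterol regulation and uptake were higher by label as a list, and not in the authors' table. All 16 tested members were positive, with a median of 0.35 (camera adjusted p = 0.00636; adjusted p = 0.734 with an estimated correlation), and 0 passed over all genes or when adjusted over the list alone. After a loess correction on transcript length, chosen after seeing the data, the median was 0.19 with 13 of 16 positive (camera adjusted p = 0.0219; adjusted p = 0.733 with an estimated correlation). The list level differed by 0.39 by label and by 0.21 without the library labelled control 1. Srebf2, the transcription factor of sterol synthesis, differed by 0.72 ± 0.28 (log2, SE), Insig1, which retains that factor's precursor, by 0.31 ± 0.23, and Npc2 by 0.14 ± 0.11. In the authors' deposited table the median was 0.0091 and the mean −0.05 (cameraPR adjusted p = 0.626), Insig1 was at −0.24 and Srebf2 at 0.037. Fatty acid synthesis genes were also higher by label: 13 of 14 members were positive, with a median of 0.47 (camera adjusted p = 0.00218; adjusted p = 0.598 with an estimated correlation). Scd2, a fatty acid desaturase, stood at 1998 ± 904 and 3347 ± 285 TPM and Fads1 at 1139 ± 154 and 1446 ± 71.6 TPM. The level of that list differed by 0.43 by label and by 0.27 without the library labelled control 1. The authors' table gave it a median of 0.032 (cameraPR adjusted p = 0.516). Cholesterol efflux and turnover was not called by label (13 of 16 positive, camera adjusted p = 0.424) or in the authors' table (median −0.0044, cameraPR adjusted p = 0.847). Its members Abca1, the cholesterol exporter, and Apoe, the main brain lipid carrier, differed by 0.58 ± 0.20 and −0.21 ± 0.22 by label. Clu, another apolipoprotein, differed by 0.15 ± 0.15, and Abca1 was at −0.15 in the authors' deposited table.

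Among cell types, astrocyte genes were higher and neuron genes lower by label. All 16 astrocyte genes were positive, with a median of 0.47 (camera adjusted p = 8.58e-05; adjusted p = 0.598 with an estimated correlation). With limma p adjusted over the list alone 8 rose, against 0 over all genes: Glul, Gja1, Gjb6, Slc1a3, Aqp4, Fgfr3, Slc4a4 and Acsbg1. Glul, glutamine synthetase, differed by 0.62 ± 0.20 (log2, SE), Aqp4, a water channel, by 0.46 ± 0.15, Slc1a2, a glutamate transporter, by 0.47 ± 0.20, and Aldoc by 0.36 ± 0.15. All 15 neuron genes were negative, with a median of −0.51 (camera adjusted p = 1.94e-08; adjusted p = 0.598 with an estimated correlation). Of these 9 fell when adjusted over the list alone, against 0 over all genes. Snap25, a synaptic vesicle fusion protein, differed by −0.62 ± 0.18 and Camk2a by −0.31 ± 0.29. In the authors' deposited table the astrocyte median was 0.068 (cameraPR adjusted p = 0.0139) and the neuron median −0.19 with all 15 members negative (cameraPR adjusted p = 0.00237). Oligodendrocyte genes had a median of −0.08 by label (camera adjusted p = 0.226), with Cnp at 0.097 ± 0.20. Their median was −0.14 in the authors' table (cameraPR adjusted p = 0.00639). Precursor genes had a median of 0.14 by label (camera adjusted p = 0.807), with Olig1 at 0.19 ± 0.14 and Bcas1 at −0.093 ± 0.18. Their median was −0.15 in the authors' table (cameraPR adjusted p = 0.0033). Longer transcripts had larger fold changes by label (Spearman rho 0.464 across genes). The deviation of a library from the mean of all 6 correlated across genes with log transcript length at −0.475 and −0.447 in those labelled control 1 and control 3 and at 0.215 to 0.422 in the other 4.

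The lists of the remaining cell types summed to fewer TPM than those above. The microglia list was lower by label, with 15 of 16 members negative and a median of −0.83 (camera adjusted p = 1.39e-04; adjusted p = 0.598 with an estimated correlation). Without the library labelled control 1 the median was −0.48 over 13 tested members (camera adjusted p = 0.0522). Without the library labelled control 3 it was −1.41 over 17 tested members. The median was −1.66 without the libraries labelled control 3 and PLX5622 3 and −1.57 with them exchanged (adjusted p = 0.665 and 0.0607 with an estimated correlation), choices made after seeing the data. Its member Sall1, which other brain cells also express, differed by 0.51 ± 0.15. The border macrophage list cannot be read here, because its 3 tested members, Cd74, H2-Ab1 and H2-Aa, all act in antigen presentation and were high in a single library. They stood at 27.0, 20.2 and 11.4 TPM in the library labelled control 3 against at most 2.40, 2.19 and 1.19 TPM in the other 5. Of 8 tested ependymal and choroid plexus genes 6 were negative (camera adjusted p = 0.0435; adjusted p = 0.598 with an estimated correlation), and Tmem212 and Ccdc153 fell when adjusted over the list alone. After a loess correction on transcript length, chosen after seeing the data, this call was lost (camera adjusted p = 0.295, median −0.24). It was also lost without control 1, control 3, PLX5622 2 or PLX5622 3 (camera adjusted p = 0.0946, 0.0884, 0.108 and 0.0529). Without control 2 or PLX5622 1 the call stayed (camera adjusted p = 0.0219 and 0.0135). Ttr, a choroid plexus transcript, ranged from 2.09 TPM in the library labelled PLX5622 3 to 302 TPM in that labelled control 1, and Rarres2 differed by −0.23 ± 0.14. Endothelial genes had a median of −0.36 (camera adjusted p = 0.134), with Slc2a1 at 0.21 ± 0.11 and Itm2a at 0.02 ± 0.19. Mural genes had a median of −0.22 (camera adjusted p = 0.113), with Pdgfrb at 0.22 ± 0.24 and Acta2 at −0.20 ± 0.30. In the authors' deposited table endothelial and mural medians, over 12 and 6 members against 5 each by label, were −0.16 and −0.29 (cameraPR adjusted p = 0.019 and 5.75e-04). The ependymal median there, over 10 members, was −0.026 with a mean of 0.029 (cameraPR adjusted p = 0.818). With the libraries labelled control 3 and PLX5622 3 exchanged, endothelial and mural levels differed by −0.088 and −0.29. Without the library labelled PLX5622 2 these differences were −0.0013 and −0.074. The Csf1r axis list was not called by label (camera adjusted p = 0.164) or by cameraPR on the authors' table (adjusted p = 0.112). Il34, a ligand of Csf1r, differed by −0.56 ± 0.18 and Csf1, the other ligand, by 0.26 ± 0.18 by label.

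Reactive and interferon genes were higher in the authors' table; by label interferon genes were lower and reactive genes were not called. Of 21 reactive astrocyte genes in the authors' deposited table, 19 were positive, with a median of 0.53 (cameraPR adjusted p = 2.26e-27). C4b, Gbp2 and Serpina3n, at 0.65, 1.54 and 0.76 in the authors' table, rose when adjusted over the list alone and 0 passed over all genes. Gfap, the intermediate filament of astrocytes, was at 0.80 in the authors' table (SE 0.28, 95% interval 0.25 to 1.36), which missed its adjusted threshold, and at 0.83 ± 0.33 by label. Of 16 interferon genes in the authors' table, 15 were positive, with a median of 0.44 (cameraPR adjusted p = 4.19e-14), and Oasl2 at 1.49 rose when adjusted over the list alone. In the limma fit with the libraries labelled control 3 and PLX5622 3 exchanged, reactive and interferon lists had adjusted p = 0.173 and 0.415 with an estimated correlation. By label, reactive genes had a median of −0.067 (camera adjusted p = 0.44). Their level was 3.56 in the library labelled control 3 against 2.63 to 3.01 in the other 5. Without that library their level difference went from −0.097 to 0.21 by label and from 0.48 to 0.27 in the exchanged grouping. Interferon genes were lower by label, with 12 of 15 negative and a median of −0.32 (camera adjusted p = 0.00351; adjusted p = 0.706 with an estimated correlation). The library labelled control 3 carries this: its interferon level was 4.08 against 3.00 to 3.36 in the other 5, and without it the difference by label went from −0.31 to 0.0022 (camera adjusted p = 0.518). With that library on the PLX5622 side, as in the exchanged grouping, the difference was 0.41, and 0.13 without it. Without both libraries in doubt the median was 0.0082 (camera adjusted p = 0.932). Vim and C4b differed by 0.26 ± 0.15 and 0.29 ± 0.26 by label, and Ifi27 and Ifitm3 by −0.26 ± 0.19 and −0.48 ± 0.34. The library labelled control 3 had the highest level of several of these genes, with Gbp2 at 14.3 TPM, Bst2 at 67.1 TPM and Psmb8 at 30.9 TPM against at most 3.88, 21.9 and 7.66 TPM in the other 5.

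**Figure D4:**
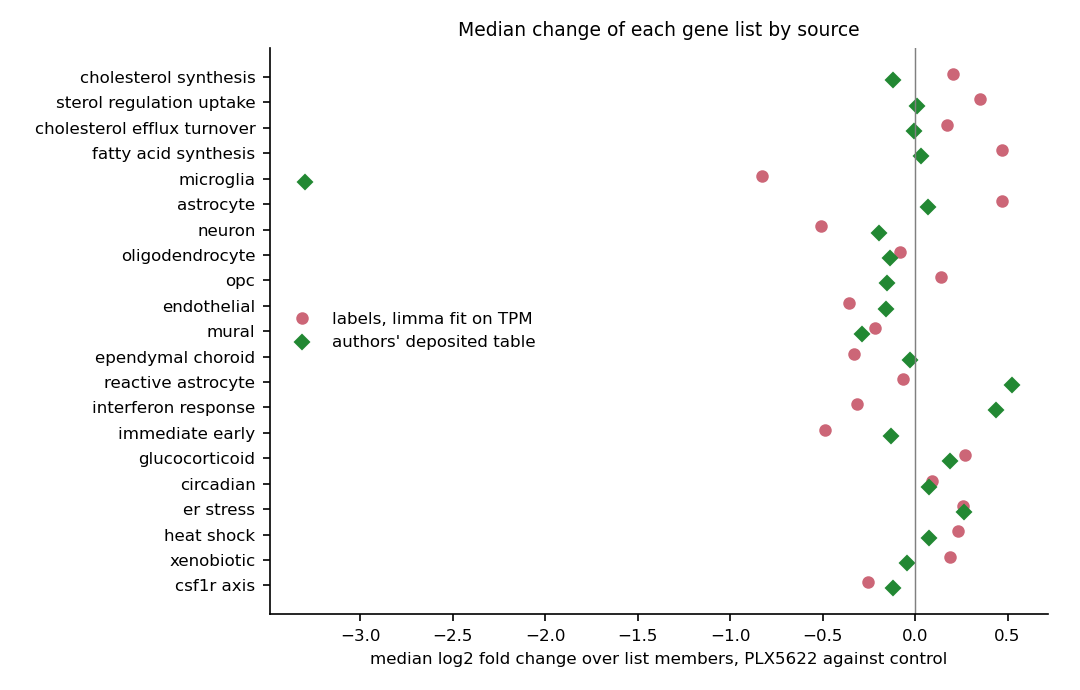
Median log2 fold change of each gene list (x axis) for PLX5622 against control, by label from the limma fit (circles) and in the authors' deposited table (diamonds). Cholesterol synthesis lies at 0.21 by label and −0.12 in the authors' table, and microglia at −0.83 and −3.30. The values by label carry the added 1 TPM, which shrinks the change of low genes. With 0.1 TPM added the microglia median by label was −1.47. The median over all tested genes was 0.089 by label, and over all genes −0.017 in the authors' table. The sources also cover different members of a list, for microglia 16 by label and 21 in the authors' table.

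Of the other state lists, immediate early genes were lower by label, with 11 of 12 negative and a median of −0.49 (camera adjusted p = 6.22e-04; adjusted p = 0.598 with an estimated correlation). Junb and Egr1, activity-induced transcription factors, differed by −1.07 ± 0.33 and −0.64 ± 0.32, and cameraPR on the authors' table gave an adjusted p = 0.362. Without the library labelled control 1 the list was not called (camera adjusted p = 0.0522). Circadian genes were not called by label (camera adjusted p = 0.59), although Ciart at −1.25 and Arntl at 0.90 passed when adjusted over the list alone. Dbp and Nr1d1, of the clock output and its repressor arm, differed by −0.38 ± 0.15 and 0.24 ± 0.14, and the authors' table gave cameraPR adjusted p = 0.108. The glucocorticoid list was not called by label (camera adjusted p = 0.729), and Sult1a1 at 0.74 passed when adjusted over the list alone. Mt1 and Mt2, metallothioneins, differed by −0.35 ± 0.25 and −0.42 ± 0.24, and the list was higher in the authors' table (median 0.19, cameraPR adjusted p = 0.0115). The library labelled PLX5622 2 sets that direction: in the exchanged grouping the level differed by 0.20, and by −0.030 without it. ER stress genes were not called by label (camera adjusted p = 0.929), with Hspa5, the ER chaperone, at 0.63 ± 0.26, Atf4 at −0.11 ± 0.18 and Asns at −0.78 passing when adjusted over the list alone. In the authors' table they were higher (median 0.26, cameraPR adjusted p = 5.75e-04). That rise is mostly of the library labelled PLX5622 2, with a level of 6.14 against 5.57 to 5.72 in the other 5 and Hspa5 at 685 TPM against 252 to 374 TPM. In the exchanged grouping the level differed by 0.23, and by 0.068 without it. Heat shock and xenobiotic lists were not called by label (camera adjusted p = 0.424 and 0.736) or in the authors' table (cameraPR adjusted p = 0.178 and 0.602). Their members Hspa8 and Hspe1 differed by 0.11 ± 0.24 and −0.25 ± 0.18 by label, and Gstm1 and Gsta4 by 0.17 ± 0.13 and −0.33 ± 0.17. Sex-linked genes were not tested as a list: Ddx3y and Eif2s3y, on the Y chromosome, differed by 0.38 ± 0.16 and 0.35 ± 0.20, and Ddx3y was at 12.5 to 21.4 TPM in all 6 libraries. Of the blood list 1 gene had values and it was not tested.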

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

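The alternatives chosen only after seeing the data were leaving out or exchanging the libraries labelled control 3 and PLX5622 3, removing genes that overlap ribosomal RNA, and cameraPR on the authors' statistic; the correction on transcript length, given with the results it bears on, was also chosen then. Of the values of named genes under the alternatives, 1094 kept their direction and their side of the threshold and 92 passed it in the same direction. A further 38 changed direction, and 26 changed sign from a main value under its SE without passing. The 92 passes can come only from alternatives that called any gene. These were array weights, the authors' table, and the fits without control 2, without PLX5622 1 and without the libraries labelled control 3 and PLX5622 3. Of the tests of 22 lists 268 kept both, 16 gained and 35 lost the call, 14 changed direction with a call in the main or the alternative fit and 13 with a call in neither, the direction being relative to all other genes except for fry. Of the list level differences 226 kept their sign, 13 changed it from a main difference under its SE and 3 from a larger one, among them the xenobiotic level under size-factor scaling (−0.0034). The call count stayed at 0 in both directions under the other pseudocounts, filters and scalings and under robust or untrended empirical Bayes. With array weights limma called 4997 genes higher and 3543 lower, with a weight of 349 for the library labelled control 3 against 0.103 to 1.54 for the others; the weight fit stopped before it converged, so these values carry little. There Csf1r (1.05), P2ry12 (0.31), Tmem119 (0.80), Bcas1 (0.19), Vim (−0.036) and C4b (−0.43) changed direction; the cause was not tested. Leaving out 1 library gave 0 to 2600 genes higher and 0 to 1154 lower, the highest without control 2, where diet and the transcript length trend cannot be told apart. It gave an adjusted p of 0.0121 to 0.912 for cholesterol synthesis (lowest without PLX5622 2) and of 1.69e-18 to 0.0522 for microglia (highest without control 1); fewer samples entered each of these fits. Of 9 lists called by camera with the preset correlation, 0 were called with an estimated correlation and 0 by fry. The microglia list had adjusted p = 0.598 and 0.509 there, and 0.312 with a minimum of 5 TPM, which leaves fewer of its genes. The replicate numbers did not pair the libraries: same-numbered deviations correlated at −0.033, −0.272 and −0.147, and a replicate block called 0 genes higher and 0 lower by limma, with 2567 at p under 0.05.

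Without the libraries labelled control 3 and PLX5622 3, limma called 2 genes higher and 12 lower, Ttr was at 0.14, and reactive astrocyte genes were higher (camera adjusted p = 0.0186; adjusted p = 0.665 with an estimated correlation). With the same libraries exchanged, limma called 0 genes, 53 had p under 0.05, and these changed direction: Ppp1r9a (−0.092), Sqle (−0.097), Insig1 (−0.16), Abca1 (−0.077), Slc1a2 (−0.076), Hmgcs1 (−0.0076), Msmo1 (−0.093), Cd74 (0.83), H2-Ab1 (0.78), Ttr (2.21), Ifi27 (0.066), Ifitm3 (0.48), Mt1 (0.063), Mt2 (0.034), Dbp (0.092) and Il34 (0.023). Cnp, Pdgfrb and Atf4 changed sign there from values under their SE. In that fit the lists that changed direction, with camera adjusted p at the preset and the estimated correlation, were cholesterol synthesis (1.28e-04 and 0.532), sterol regulation and uptake (0.699 and 0.945), the antigen presentation genes of the border macrophage list (0.080 and 0.532), precursors (0.00268 and 0.532), ependyma (0.861 and 0.945), reactive astrocytes (5.78e-17 and 0.173) and interferon response (1.28e-09 and 0.415). Efflux and xenobiotic lists changed sign without a call in either fit. The border macrophage and ependymal levels turned to 0.79 and 0.28. The authors' deposited table calls 14 genes lower, and in it the direction by label changed for Sptbn1 (−0.066), Ppp1r9a (−0.16), Sqle (−0.15), Insig1 (−0.24), Abca1 (−0.15), Slc1a2 (−0.13), Hmgcs1 (−0.085), Msmo1 (−0.15), Fads1 (−0.0077), Cd74 (2.57), H2-Ab1 (1.97), Ttr (0.46), Ifitm3 (0.39), Dbp (0.057) and Nr1d1 (−0.011). Clu, Cnp, Itm2a, Pdgfrb and Atf4 changed sign there from values under their SE. By cameraPR on the authors' table the lists that changed direction were cholesterol synthesis (adjusted p = 5.75e-04), sterol regulation and uptake (0.626), precursors (0.0033), ependyma (0.818), reactive astrocytes (2.26e-27) and interferon response (4.19e-14), and efflux and xenobiotic lists changed sign without a call in either. The removal of mitochondrially encoded genes and the tests for counts were planned and not run, since no tested gene was mitochondrially encoded and counts were not used here. Depth per library is unknown, so it limits the text to values without counting error.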

Other observations

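All tests in this part were chosen after the results they bear on were seen. Fcer1g and Fcgr3, myeloid genes outside the microglia list, were lowest in the same libraries as the list itself. Both are among the authors' calls, whose fold changes set these libraries against the others, so this is no separate evidence. Fcer1g was at 5.86 and 2.25 TPM in the libraries labelled control 1 and control 2, at 0.209 TPM in control 3, at 0.398 TPM and listed at 0 in PLX5622 1 and PLX5622 2, and at 0.903 TPM in PLX5622 3. Fcgr3, an antibody receptor, was at 3.32, 1.86 and 0.339 TPM in the control libraries and at 0.310, 0.149 and 0.527 TPM in the PLX5622 libraries. The antigen presentation genes Cd74 and H2-Ab1 did not: both stood highest, at 27.0 and 20.2 TPM, in the library labelled control 3, which had Csf1r at 0.118 TPM, where they exceeded the other 5 libraries. In the libraries labelled control 1 and control 2, Cd74 was at 2.40 and 1.71 TPM and H2-Ab1 at 2.07 and 1.95 TPM. Genes that overlap ribosomal RNA sequence (Rn45s, Mir6236 and Lars2) took 3.47% of TPM in the library labelled control 2 and 0.204% to 1.08% in the other 5.

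The first pattern is the low microglial signal of the library labelled control 3 beside the signal in the library labelled PLX5622 3. Some values run with the labels: control 3 correlates most with control 1 (0.9916) and PLX5622 3 with PLX5622 2 (0.9939), and p under 0.05 is reached by 2974 genes by label and 53 with the libraries exchanged. Control 2, against its label, correlates most with PLX5622 1 (0.9966). Control 1 and control 3 are also the libraries whose deviation runs against transcript length (−0.475 and −0.447). The correlations between libraries were not repeated after the length correction. A single grouping shared by both deposited tables, with uneven removal of microglia, is argued against by the correlation of 0.567 between the labelled split and the authors' fold changes across genes outside the microglial lists. An exchange of these headings between the tables is a candidate explanation: that split reached 0.9998, against 0.567 for the highest of the other 9. Which of the tables carries the intended heading stays open, since no source used here settles it, and uneven removal within the other libraries was not tested.

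The second pattern is the lower neuron and higher astrocyte list by label. For the neuron list a transcript length trend as the whole cause is argued against by size only. Its median went from −0.51 to −0.65 after a loess correction on length. Its camera adjusted p there was 1.44e-08, and 0.704 with an estimated correlation. That call does not decide this, since the preset correlation called 6 to 12 lists in each of the 10 splits. The astrocyte list stayed called at the preset correlation (camera adjusted p = 4.31e-06; adjusted p = 0.704 with an estimated correlation), with a median that fell from 0.47 to 0.32, so the trend may account for part of it. In that fit limma called 0 genes and 2930 had p under 0.05. A higher astrocyte share that lowers all other types alike is argued against, by label only, by the neuron minus oligodendrocyte level, which differed by −0.44 between labels (exact p = 0.1, the smallest possible; pairs from −0.71 to −0.087). With the libraries labelled control 3 and PLX5622 3 exchanged it differed by −0.042 (pairs from −0.64 to 0.60), so this stays open while the headings are in doubt. Exchanged headings and an effect of diet cannot be told apart here: without the libraries in doubt the neuron median was −0.45, with an adjusted p of 0.665 by the estimated correlation in 2 libraries against 2. With those libraries exchanged the neuron and astrocyte medians were −0.15 and 0.15, against −0.51 and 0.47 by label. In the exchanged grouping the neuron level difference of −0.12 turned to 0.10 without PLX5622 2 and to 0.018 without control 2. The astrocyte level difference of 0.18 turned to −0.056 without control 1. Leaving out any other library kept these signs.

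The third pattern is the spread of the cholesterol synthesis level among libraries of 1 label, a pooled SD within labels of 0.220. A transcript length trend may account for part of it but is argued against as the whole cause, since that SD was 0.171 after the length correction (0.122 from 0.218 for control, 0.209 from 0.222 for PLX5622). Scaling by reads of the genes that overlap ribosomal RNA is argued against, since it was 0.234 once they were removed. No biological explanation was tested, and a difference between animals stays open.

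For chance, the 6 libraries have 10 splits, too few for a share under 0.05. Limma called 0 genes in the labelled split and at most 0 in another, so that count cannot bear on chance. An unadjusted p under 0.05 was reached by 2974 genes in the labelled split and by at most 2084 in another. Lists called by camera numbered 9 in the labelled split and 12 in the highest other, and 7 of the 10 splits gave as many.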
